A study of Mus musculus with 2 samples.

How the data were processed

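MicroRNA sequencing libraries from E12.5 mouse forebrain, 2 biological replicates of 1 group, were analysed from the deposited gene counts. Per the labels, the pools came from 120 and 68 embryos of both sexes and RNA below 30 nt was used. The labels give a separate biosample for each pool and 1 common donor record, so the replicates are 2 pools of embryos of 1 strain. Each pool gave 1 library. Differences between the pools can therefore not be told apart from differences in dissection, library preparation or sequencing. Per the notes deposited with the files, the authors derived the gene counts from alignments to mm10 with genome annotation M4. The aligner, the counter, adapter trimming and the treatment of reads with several matches are not given in the sources used here.

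Each deposited table holds raw read counts, not normalised, for both strands together, for the strand of the gene and for the opposite strand. Which column is which was read from the values. The both-strand count equalled the sum of the other 2 columns in every gene, and 97.3% and 97.2% of assigned reads lay in the column taken as the gene strand. The first 4 rows name no gene and were left out of library sizes and tests. They held 17.5% and 16.8% of all reads as unmapped, 37.95% and 37.87% as matching several places, 5.49% and 5.93% as lying in no feature on the gene strand, and 0 as ambiguous. Reads that match several places therefore stand outside the gene counts. This can lower the levels of genes whose mature miRNA has identical copies, by an amount that cannot be read from the files.

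Gene symbols, positions and hairpin sequences were taken from GENCODE M21, which uses the same genome build, by Ensembl ID without version. Of 1973 genes, 1894 matched, all of them miRNA genes in M21, and 1815 had the same version. The 79 unmatched genes held 13 and 4 reads. M21 has 308 miRNA genes with no row in the tables. A hairpin was said to share a stretch where at least 20 bases occurred in another M21 hairpin, which was so for 923 genes. A genome sequence was not used here, so uniqueness over the whole genome was not examined. Positions are 1-based.

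CPM were computed over gene-strand assigned reads, and log ratios on log2(CPM + 1). The floor for a gene without reads is that of 3 counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers in the sources used here. The design, the 20 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 25 most abundant genes, up to 4 members with the highest CPM in each list, the 5 highest and 5 lowest replicate ratios among genes of at least 10 CPM, the 5 genes with the highest opposite-strand share among those with at least 100 reads on both strands, where ties were ordered by reads, and the 5 neighbouring pairs with the largest difference in level. The lists were let-7 and miR-98; miR-125, miR-99 and miR-100; miR-17~92 and its paralogues; neural; oligodendrocyte; pluripotency; Dlk1-Dio3; repeat-rich families; DROSHA-independent; erythroid; leukocyte; endothelial; mesenchymal; muscle; endoderm; epithelial; eye and sensory; Hox; multiciliated; and X-linked testis.

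With 1 group of 2 samples no contrast could be fitted with edgeR's quasi-likelihood test. The common dispersion was estimated with edgeR 4.0.16 in R 4.3.3 on 403 genes with at least 10 reads in both libraries, with a bootstrap range over 100 draws of genes. Each of 511 genes with at least 10 reads in both libraries together was compared between the libraries with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a 2-fold difference in CPM. The medians of lists were placed among 10000 random lists, matched on level in 10 bins for replicate ratios, for lists with at least 3 members of at least 1 CPM. Neighbouring genes were compared by a permutation test with 10000 shuffles. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 was used.

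The steps were tested on simulated data. With counting error only, Fisher's test called 88 of 100 genes changed 3-fold, 91 of 100 changed 6-fold and 1 of 311 unchanged genes, over 511 genes. With the estimated variation between libraries it called 84 of 100 changed 3-fold, 92 of 100 changed 6-fold and 8 of 311 unchanged genes. This variation was 1 common value for every gene, estimated from the same libraries. Simulated coefficients of variation of 0.1 and 0.2 were returned as 0.097 and 0.189 over 403 genes. Of 100 simulated lists without a shift, 11 lay outside the central 95% of random lists, and in a larger run added later, 113 of 2000 did, or 5.65%. Alternatives covered the both-strand column, edgeR's TMM scaling and DESeq2 1.42.0 size factors, minimum reads and CPM, pseudocounts of 0.1 and 10, and neighbour distances. They also covered taking the most abundant gene out of the library size and leaving out each replicate. Crediting opposite-strand reads to the gene annotated there, the both-strand column for the dispersion and a fit on hairpin GC content were added after seeing the data.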

Results

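MicroRNA sequencing was carried out on forebrain from mouse embryos of the B6NCrl strain at embryonic day 12.5, a stage at which neural progenitors still divide and the first neurons are being formed. MicroRNAs (miRNAs) are short RNAs, cut from hairpin precursors, that lower the output of target messenger RNAs. The series held 1 group with 2 biological replicates, each a pool of both sexes. Replicate 1 came from 120 embryos and replicate 2 from 68 embryos, and both libraries were made from RNA below 30 nt. No contrast between tissues or ages was part of the design, so the question addressed was which miRNA genes were read in this tissue, and how closely the pools matched. The libraries held 11104730 and 11154304 reads, of which 4333194 and 4397107 were assigned to a miRNA gene on its own strand. Levels are given as counts per 1000000 of these assigned reads (CPM), as mean ± SD of 2 replicates. A gene with 0 reads could have had up to 0.692 CPM in replicate 1 and 0.682 CPM in replicate 2, and such floors cover counting error only.

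The forebrain libraries were led by Mir99a at 126269 ± 10384 CPM (SD, n = 2), followed by Mir335 at 77130 ± 2497 CPM and Mir17 at 60649 ± 594.7 CPM. Mir99a (ENSMUSG00000065530.1) lies on chromosome 16, from 77598936 to 77599000 of mm10, in an intron of the non-coding host gene Mir99ahg. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6, from 30741299 to 30741396, in an intron of the imprinted gene Mest. Mir17 (ENSMUSG00000065508.1) lies on chromosome 14, from 115043671 to 115043754, in an exon of Mir17hg, the host transcript of the miR-17~92 cluster. Mir130a reached 35501 ± 808.3 CPM, Mir99b 29722 ± 660.6 CPM, Mir30e 29161 ± 2341 CPM and Mirlet7g 25690 ± 557.3 CPM. The next places were taken by Mir20a, Mir93, Mir100, Mir26b, Mir149, Mir92b, Mir126a, Mir106b, Mirlet7i, Mir322, Mir487b, Mir30a, Mir342, Mir181c, Mir130b, Mir18, Mir181d and Mir423, the last of which stood at 9259 ± 69.78 CPM. Mir487b shares a stretch of at least 20 bases with 1 other annotated hairpin, so its level is uncertain. The ranking covers assigned reads on the gene strand. In the both-strand column 24 of the 25 genes stayed among the first 25 and Gm24321 entered, and with opposite-strand reads credited 24 stayed too. Reads that matched several places stood outside the ranking, 4213961 and 4224434 against 4333194 and 4397107 assigned. The places of genes with identical copies, and the shares held by the most abundant genes, are therefore uncertain. The single most abundant gene held 12.6% ± 1.04 of assigned reads (SD, n = 2), the 10 most abundant 45.4% ± 0.807, and the 50 most abundant 83.0% ± 0.00883. Of 1973 annotated genes, 403 had at least 10 reads in both libraries and 1210 had none in either. A mean of at least 1 CPM was reached by 521 genes, of at least 100 CPM by 229 genes and of at least 1000 CPM by 101 genes. With a minimum of 1 read in both libraries in place of 10, 652 genes were detected.

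**Figure D1:**
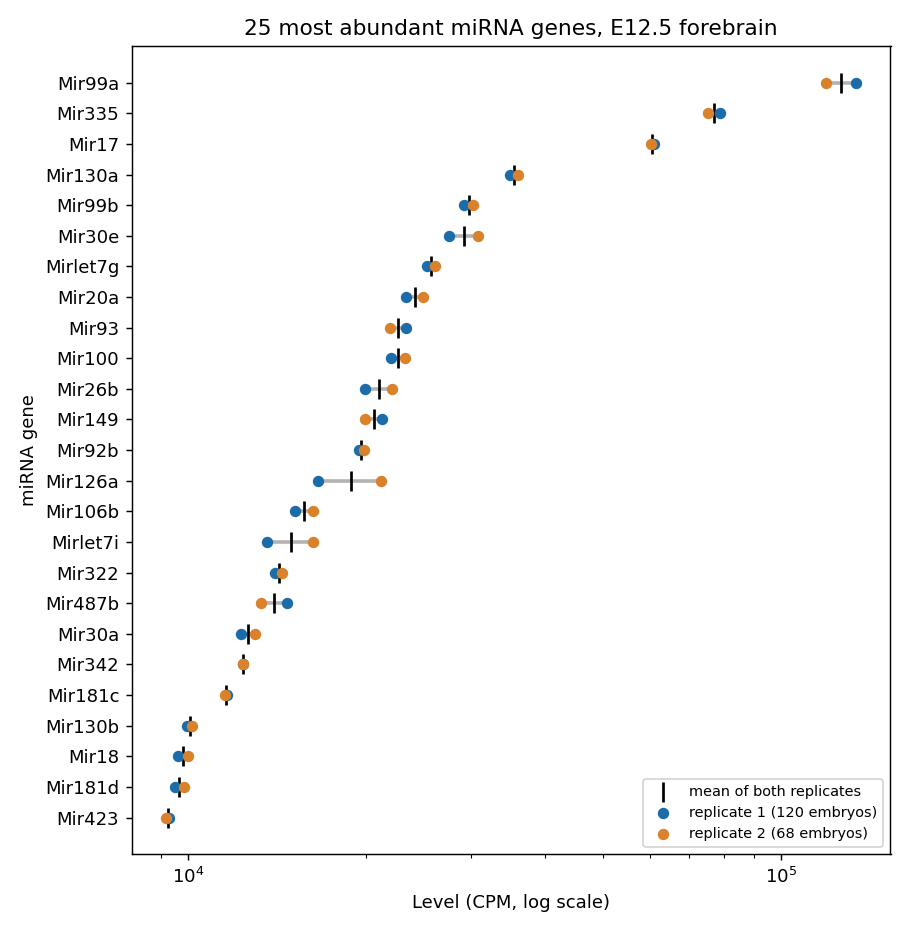
Level of the 25 most abundant miRNA genes in CPM on a log axis, with 1 point for each replicate, a black tick at their mean and a grey line joining the replicates. Mir99a leads in both replicates, and Mir126a and Mirlet7i are among the genes with the widest gap between replicates.

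The miR-125, miR-99 and miR-100 group, which is hosted in part by the same transcripts as let-7 genes, held the largest share of the 20 lists of miRNA genes examined, 18.7% ± 0.893 of assigned reads (SD, n = 2). All 6 members were detected, including Mir99a, Mir99b, Mir100 at 22632 ± 845.3 CPM and Mir125a at 4794 ± 27.28 CPM. Of the 6, 2 share a stretch with another hairpin, against 15 of 20 in the neural list. The order of the lists therefore holds for assigned reads only. The let-7 and miR-98 family, which limits proliferation and accumulates as tissues mature, held 4.69% ± 0.268, most of it in Mirlet7g and Mirlet7i, with Mirlet7d at 2775 ± 52.1 CPM and Mir98 at 2101 ± 181.2 CPM. Of its 10 genes with counts, 5 share a stretch with another hairpin, and Mirlet7e and Mirlet7f-1 had no row of their own. The share of the family and its make-up are therefore uncertain. Reads on the strand of Mirlet7e, counted opposite to Gm25927, stood at 4315 ± 500.4 CPM, above Mirlet7d. With opposite-strand reads credited the family held 4.98%. The miR-17~92 cluster and its 2 paralogous clusters, which promote proliferation of progenitor cells, held 14.8% ± 0.142, and all 15 members were detected. Mir20a stood at 24125 ± 1104 CPM, Mir93 at 22647 ± 992.3 CPM and Mir106b at 15720 ± 768.8 CPM, the last 2 lying in the cell-cycle gene Mcm7. The Dlk1-Dio3 imprinted cluster of chromosome 12, expressed from the maternal chromosome and abundant in brain, held 8.90% ± 0.261, with 47 of 51 genes detected. Its highest members with a row were Mir487b at 13996 ± 1033 CPM, Mir127 at 8663 ± 656.8 CPM, Mir369 at 8554 ± 285.7 CPM and Mir431 at 7500 ± 527.5 CPM. For 7 further members, Mir409, Mir376a and Mir380 among them, no row was present. Reads on the strand of Mir409, counted opposite to Gm24321, stood at 10292 ± 256.6 CPM, above Mir127. With opposite-strand reads credited, which added 6 members, the cluster held 10.4%.

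The neural progenitor and neuron list held 1.23% ± 0.0752 of assigned reads (SD, n = 2), with 18 of 20 members detected. Mir137 was highest at 5207 ± 112.5 CPM, followed by Mir153 at 2777 ± 745.1 CPM, Mir7b at 1260 ± 205.2 CPM and Mir9-3 at 713.5 ± 0.5506 CPM. Of the 20 members, 15 share a stretch with another hairpin, Mir9-3 included, and reads that matched more than 1 place were 46.0% and 45.5% of mapped reads and stood outside the gene counts. Levels of the miR-9, miR-124, miR-128 and miR-138 genes are therefore uncertain. The oligodendrocyte lineage list held 0.114% ± 0.00807, led by Mir219a-1 at 880.6 ± 10.65 CPM, followed by Mir219a-2 at 144 ± 66.87 CPM and Mir338 at 117.2 ± 3.161 CPM. Mir219a-1 and Mir219a-2 each share a stretch with another hairpin, and Mir219a-2 stood at 96.7 CPM in replicate 1 and 191.3 CPM in replicate 2. The miR-302 and miR-290 clusters, typical of pluripotent and early embryonic cells, held 0.221% ± 0.0106. Mir302a stood at 822 ± 37.49 CPM and Mir302d at 726.4 ± 26.66 CPM, and 7 of 12 members were detected. The miRNAs made without DROSHA held 0.435% ± 0.0385, led by Mir484 at 3214 ± 297.2 CPM and Mir320 at 666.4 ± 31.82 CPM. The repeat-rich families held 0.425% ± 0.0375, led by Mir467c, in an intron of Sfmbt2, at 1255 ± 73.84 CPM. Because 67 of their 69 genes share a stretch with another hairpin, these levels are uncertain.

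Lists for other cell types that a dissected forebrain can hold were also read. Mir126a, which lies in Egfl7 and marks endothelial cells, stood at 18872 ± 3264 CPM (SD, n = 2), or 1.89% ± 0.326 of assigned reads. Mesenchymal and mural cell miRNAs held 1.47% ± 0.201, with Mir143 at 5873 ± 868.4 CPM, Mir140 at 4790 ± 270.2 CPM and Mir214 at 3547 ± 747.3 CPM. Epithelial miRNAs held 1.18% ± 0.256, with Mir429 at 5024 ± 1579 CPM, Mir203 at 2158 ± 343.3 CPM, Mir200b at 1504 ± 502.5 CPM and Mir200c at 1446 ± 456.4 CPM. Sensory organ and eye miRNAs held 0.544% ± 0.0381, led by Mir182 at 2625 ± 359.4 CPM and Mir183 at 1417 ± 312.4 CPM. Multiciliated cell miRNAs held 0.496% ± 0.138, most of it Mir449a at 4303 ± 1377 CPM, followed by Mir34c at 617 ± 0.3948 CPM. Lower shares were found for liver, gut and pancreas miRNAs at 0.0764% ± 0.00627, led by Mir375 at 387.3 ± 77.55 CPM, for leukocyte miRNAs at 0.0436% ± 0.00611, led among genes with a row by Mir155 at 241.4 ± 16.94 CPM, and for erythroid miRNAs at 0.0289% ± 0.00537, led by Mir451a at 248 ± 63.8 CPM. Mir142 had no row, and reads on its strand, counted opposite to Mir142b, stood at 327.9 ± 36.78 CPM, above Mir155. With them credited the leukocyte share was 0.0743%. The miRNAs of the Hox clusters, which are used behind the forebrain, held 0.0182% ± 0.000885, led by Mir10a at 70.02 ± 7.043 CPM. Muscle miRNAs held 0.0050% ± 0.00123, led by Mir208b at 18.79 ± 0.5185 CPM. Of its 9 members 4 share a stretch with another hairpin, and Mir133a-1 and Mir133a-2, which are among them, had 0 reads, so this share is uncertain. None of the 18 genes of the X-linked testis cluster was detected, and the highest, Mir741, had 2 reads in replicate 1 and 4 reads in replicate 2.

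**Figure D2:**
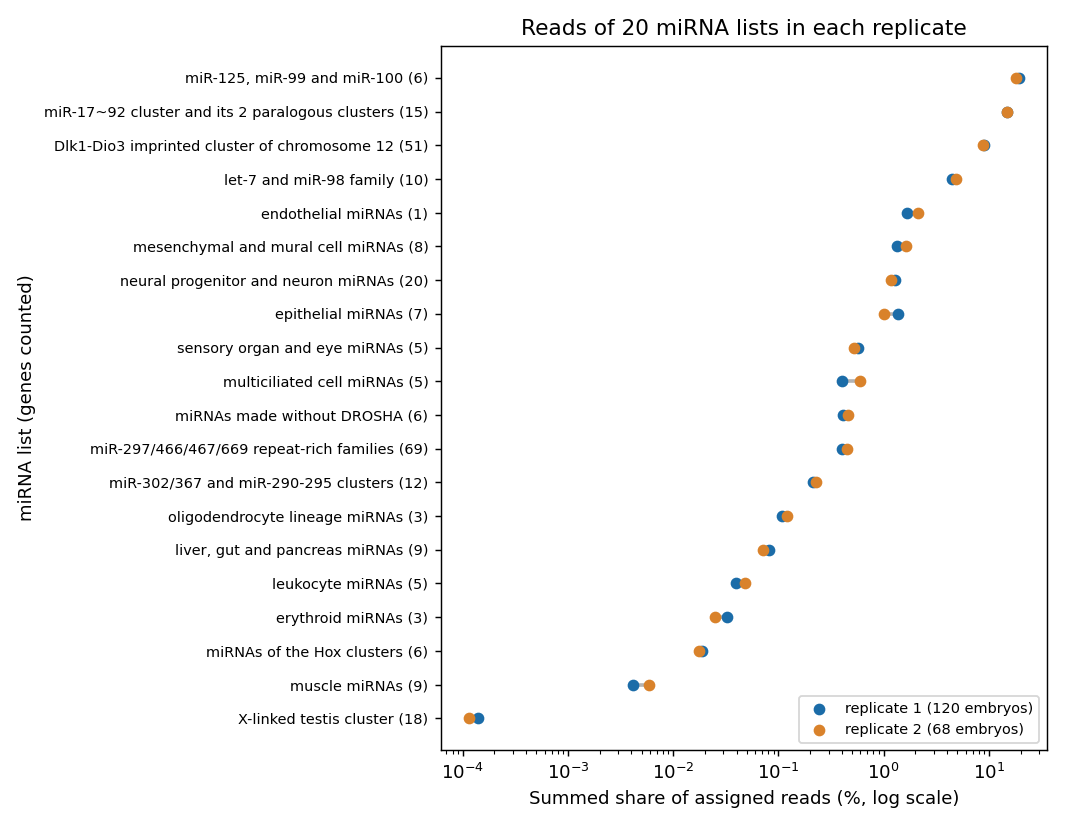
Share of assigned reads held by each of 20 miRNA lists, in percent on a log axis, with 1 point for each replicate and the number of genes counted in brackets. The miR-125, miR-99 and miR-100 group is highest at 18.7% and the X-linked testis cluster lowest, with none of its 18 genes detected.

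The levels of the 2 pools were close. Across 521 genes with a mean of at least 1 CPM, log2(CPM + 1) gave a Pearson r of 0.994 and a Spearman rho of 0.981, where genes are not independent replicates. The common biological coefficient of variation from edgeR was 16.4%, with a bootstrap range of 12.5% to 20.3% over 403 genes. With 1 library for each pool it can also hold variation from library preparation. The range comes from redrawing genes and does not cover the uncertainty of having 2 libraries. The spread was wider than counting error, with a chi-square of 75.3 per degree of freedom, so the files did not hold the same library under both names. Fisher's exact test, which compares these libraries and not conditions, found 167 of 511 genes at a Benjamini-Hochberg adjusted p under 0.05, 103 higher and 64 lower in replicate 2, and 14 of them differed by at least 2-fold. Of these 14, 11 were higher in replicate 2, among them Mir211, with 46 reads in replicate 1 and 384 in replicate 2, and Mir206, with 13 and 117 reads. The others were Mir6897, Mir5126, Gm25911, Mir297a-2, Mir6236, Mir449b, Gm26117, Gm23935 and Mir2137. Apart from Gm23935 and Mir6236, these were named after their values were seen. The 3 that were lower in replicate 2 were Mir200a, Gm23394 and the gene ENSMUSG00000092933, and the last 2 were named after their values were seen. In simulated counts with the estimated variation between libraries, 134 of 311 unchanged genes also passed the adjusted p and 8 passed with the 2-fold minimum, so these calls carry variation between libraries as well. Among genes of at least 10 CPM, 5 differed by at least 2-fold.

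By list, epithelial miRNAs stood lowest in replicate 2, with a median log2 ratio to replicate 1 of -0.65 over 7 genes, below all of 10000 random lists matched on level. The 5 miR-200 genes were lower by Fisher's exact test, with log2 ratios of -1.79 for Mir200a, -0.84 for Mir141, -0.69 for Mir200b and -0.65 for both Mir200c and Mir429. The other 2 members, the surface epithelium miRNAs Mir203 and Mir205, were higher, at 0.33 and 0.50. Mesenchymal and mural cell miRNAs were higher in replicate 2 in 7 of 7 genes, 6 of them by the same test, with a median of 0.47 at percentile 99.9. Leukocyte miRNAs had a median of 0.43 at percentile 99.4, with 1 of 4 genes higher by Fisher's exact test, Mir223 at 0.46, and Mir155 at 0.14, and multiciliated cell miRNAs a median of 0.47 at percentile 99.04, with Mir449a at 0.66 and Mir34c at -0.0013. The multiciliated list fell to percentile 86.8 when members under 10 CPM were left out. The Dlk1-Dio3 cluster had a median of -0.05 at percentile 1.16, with 31 of 47 genes lower, and no longer stood apart, at percentile 2.56, with members of at least 10 CPM. Its genes come from 1 locus and do not vary independently. Of 18 lists compared in this way, 5 lay outside the central 95% of random lists, where the nominal rate gives 0.9 lists. The number was 4 with members of at least 10 CPM and 6 with a pseudocount of 10. In simulation 11 of 100 unshifted lists lay outside, and 113 of 2000 in a larger run. The simulated genes varied independently, whereas members of a real list can come from 1 transcript. Neither these rates nor the nominal one need hold for such lists. Let-7, miR-17~92, neural, oligodendrocyte, pluripotency, muscle, erythroid, endoderm, eye, Hox, repeat-rich, DROSHA-independent and miR-125/99/100 lists lay inside. The Hox list, with a median of -0.20 at percentile 3.34, moved outside to percentile 1.30 with members of at least 10 CPM and to 1.38 with a pseudocount of 10. With 1 library for each pool these percentiles describe these libraries and are no test.

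**Figure D3:**
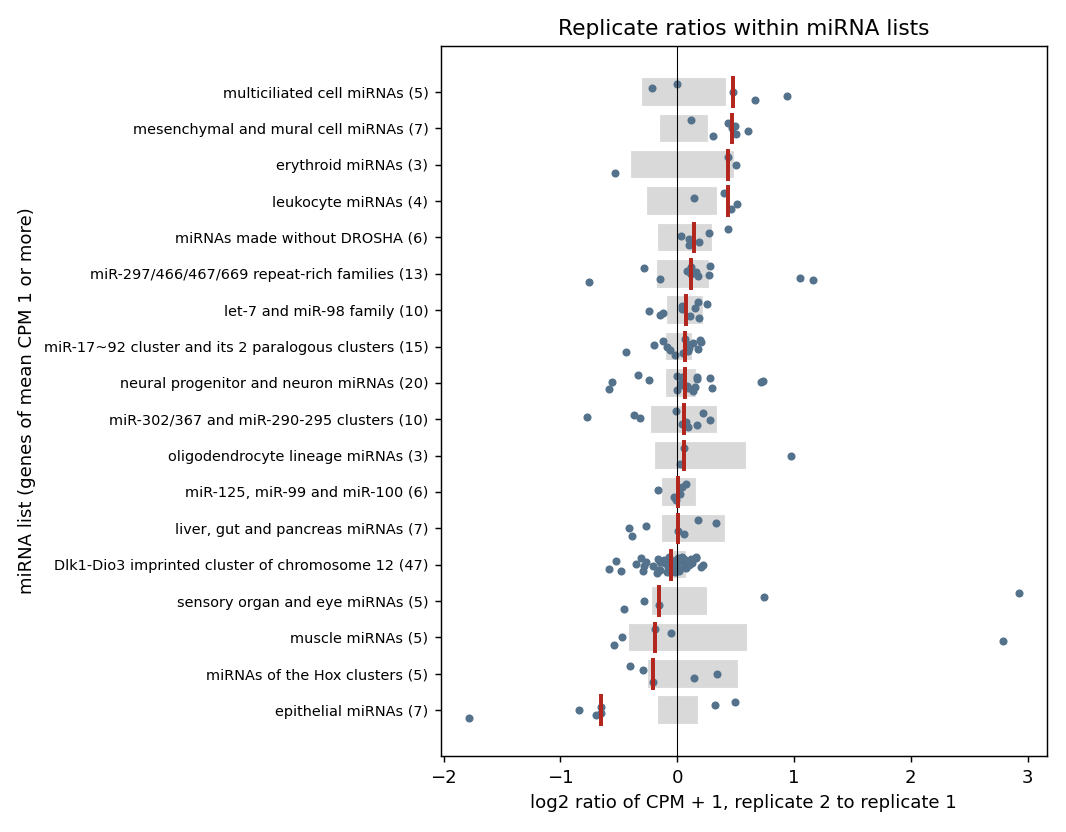
Log2 ratio of CPM + 1 in replicate 2 to replicate 1 for 18 miRNA lists, with 1 point for each gene of at least 1 CPM, a red bar at the list median and a grey band over the central 95% of random lists matched on level. The epithelial median of -0.65 lies left of its band, and the mesenchymal, leukocyte and multiciliated medians lie right of theirs.

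Neighbouring miRNA genes, which can be cut from 1 primary transcript, were closer in level than shuffled genes. Over 310 pairs on the same strand and at most 10 kb apart, the mean absolute difference in log2(CPM + 1) was 2.15, against 2.78 with shuffled levels (one-sided permutation test, p = 0.0043). Among genes of at least 1 CPM the difference was 3.38 over 130 pairs, against 4.61 with shuffled levels. With pairs at most 3 kb apart the difference was 2.36 and p was 0.0706. The shuffles moved single genes, whereas pairs of 1 cluster share genes and are not independent. Large clusters, such as those in Sfmbt2 and the Dlk1-Dio3 region, give many such pairs. Over all genes, pairs with no reads in either gene also count as close. The p-values therefore do not take loci as units, and how far the result rests on a few clusters was not tested. Single pairs still differed widely. In the Dlk1-Dio3 region, from 109588592 on chromosome 12, Mir3070b stood at 0.572 ± 0.156 CPM (SD, n = 2) beside Mir431 at 7500 ± 527.5 CPM, and Mir434 at 1653 ± 17.23 CPM lay 357 bases from Mir432, which had no reads. On chromosome 3, Mir137 stood at 5207 ± 112.5 CPM and Gm24155, 792 bases away, at 0.462 ± 0.653 CPM. Mir3070b and its copy share a stretch, so its level is uncertain.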

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

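All tests of explanations in this part were chosen after the results were seen; 1 test on sequence sharing written before the data were examined needs the genome sequence and was not run.

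Reads outside the main measurement were present in both libraries. Reads that matched more than 1 place numbered 4213961 in replicate 1 and 4224434 in replicate 2. Reads on the strand opposite to the annotated gene numbered 119609 and 125632, or 2.69% and 2.78% of assigned reads. There were no control samples, so these totals were picked out for exceeding what a count of 0 allows, which any such total does. The opposite-strand reads of both libraries together were 89840 for Gm24321 in an intron of Mirg, 37691 for Gm25927 in an intron of Spaca6, 33114 for Gm25252, 28145 for Gm24083 and 17191 for Gm25750, and each of these 5 genes had 0 reads on its own strand.

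The opposite-strand reads were concentrated in few genes. Of 328 genes with at least 100 reads, 11 had over 50% of them on the opposite strand. A loss of strand in library preparation would spread such reads over abundant genes, and the median opposite-strand share of the 100 most abundant genes was 0%. Genes whose opposite strand carries an M21 miRNA gene with no row held 99.8% of the opposite-strand reads (99.79%), so a gene missing from the counted annotation is a candidate explanation, with Mir409, Mirlet7e, Mir376a, Mir191 and Mir380 at the 5 leading places. No biological explanation was tested.

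Genes that share a stretch with another hairpin had few reads, with 89 of 923 detected against 314 of 971 without a shared stretch. That reads that match more than 1 place were not assigned to genes could be the cause, but the test made for it did not decide. The median of the 923 genes was 0 reads, at percentile 50 of random lists, and since random lists also have a median of 0 no lower value was possible. The 124 named Mir genes with 1 or 2 sharing partners had a median of 46.5 reads, at percentile 100 of random lists, against 3.5 reads in 821 without a partner, so it may be that predicted and repeat-family genes fill the set. These gene sets differ in expression, so the medians do not tell how many reads any gene lost.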

How the results depend on the processing

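The both-strand dispersion, the crediting of opposite-strand reads and the GC fit were chosen after seeing the data. Across the alternatives run, 49 values of main results stayed, 8 moved and 1 weakened, by a limit set for each kind of value. Counts stayed within a set fold change, correlations and the dispersion within their bootstrap range, and shares within 1 SD of the main value. Leaving out 1 of 2 replicates cannot take a share or a mean CPM beyond that SD, so those values could not move. Genes that differed at least 2-fold between replicates numbered 5 in place of 14 with a minimum of 10 CPM, where fewer genes were tested. Pearson r was 0.991 with a pseudocount of 0.1 and 0.997 with 10, in place of 0.994. Spearman rho was 0.960 over genes with at least 1 read in either library and 0.993 over genes of at least 10 CPM, in place of 0.981. Detected genes numbered 652 in place of 403 with a minimum of 1 read, by construction. In the both-strand column the 10 most abundant genes held 44.1% and the 50 most abundant 81.3%, since opposite-strand reads enter the total. The closeness of neighbours weakened to 2.36 (permutation p = 0.0706) at 3 kb, and the cause was not tested, while at 50 kb p was 9e-04 and among genes of at least 1 CPM it was 1e-04, the smallest the shuffles can give. Each of these p-values treats pairs of 1 cluster as separate. For named genes and single lists, 278 values stayed, 57 moved, 2 strengthened and 2 weakened. Most of those that moved came from taking the reads of Mir99a out of the library size. That step raises every CPM and share by construction, and Mir99a itself went from 126269 to 144598 CPM. Some small list medians changed sign and were still counted as stayed. For example, the endoderm median log2 ratio of 0.0035 became -0.016 with TMM scaling and -0.0303 with DESeq2 size factors. After the GC fit it was -0.0703, and the oligodendrocyte median went from 0.0546 to -0.0143. Without 1 replicate, detected genes numbered 421 to 437, and the share of the top gene was 11.9% to 13.4%. No paired analysis was possible because the series holds 1 group. Depth limits genes below about 0.692 CPM.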

Other observations

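The tests of explanations in this part were all chosen after the results were seen.

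Single genes with large replicate ratios are given here as values. The medians of the eye, muscle and erythroid lists lay inside the random band, at percentiles 5.6, 14.3 and 95.1, and 167 of 511 genes passed the same Fisher's exact test. Mir211, which lies in an intron of the melanocyte and retina gene Trpm1, stood at 10.6 CPM in replicate 1 and 87.3 CPM in replicate 2, and Mir204, in an intron of the related gene Trpm3, at 587.6 and 982.2 CPM. The other 3 genes of the sensory organ and eye list were lower in replicate 2, with log2 ratios of -0.28 for Mir182, -0.45 for Mir183 and -0.15 for Mir96. Mir206, a skeletal muscle miRNA, stood at 3.0 and 26.6 CPM, while the heart miRNAs Mir208a and Mir208b had log2 ratios of -0.48 and -0.05 and did not pass the test. Mir451a, an erythroid miRNA, had a log2 ratio of -0.53 and its neighbour Mir144 one of 0.51. Mir126a of endothelial cells had a ratio of 0.35. Mir153 of the neural list stood lower in replicate 2, at -0.55. Mir101a, which belongs to none of the lists and shares a stretch with 1 other hairpin, stood at -0.91. Gm23935, which shares a stretch with 5 other hairpins, stood at 50.5 CPM in replicate 1 and 155.1 CPM in replicate 2. Mir6236 stood at 56.3 and 142.1 CPM. Mir181a-2, which shares a stretch with 1 other hairpin, and Mir147 had log2 ratios of -0.77 and -0.75.

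The 5 miR-200 genes of 2 loci were lower in replicate 2. Counting error alone is argued against, since 5 of 5 genes passed Fisher's exact test and were lower. That is the result that singled them out, and the test does not cover variation between libraries. In simulated counts with such variation, 134 of 311 unchanged genes passed the adjusted p too. That simulation gave every gene 1 common variation estimated from these 2 libraries, so this rate need not hold for these 5 genes. A smaller share of surface epithelium in replicate 2 would be expected to lower Mir203 and Mir205 as well, but both were higher, with a mean log2 ratio of 0.41. These 2 ratios had been seen before and come from 1 library for each pool, so they are no independent test. For hairpin GC content, the linear fit, which left the median at -0.76, moved these genes no more than all others and so decided nothing by itself. Over 321 genes of at least 10 CPM, GC content and the replicate ratio had a Spearman rho of 0.0008. The 5 genes have a GC content of 49.4% to 55.1%, and Mir203 and Mir205, which were higher, of 48.7% and 50%. These values argue against a trend with hairpin GC content as the cause. Other epithelia, such as the olfactory one, may differ in share between the dissections, which stays untested, and the design gives no group to test it with.

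Mir448, Mir1264 and Mir1298, in introns of the serotonin receptor gene Htr2c on chromosome X, were higher in replicate 2, at log2 ratios of 0.70, 0.91 and 0.85, and were singled out after their values were seen. More Htr2c-expressing tissue, such as choroid plexus, in the pool of replicate 2 is a candidate explanation. The other 4 miRNA genes in Htr2c held 11 and 20 reads, all of them from Mir764 and Mir1912. Their log2 ratio was 0.65 (exact binomial p = 0.15), so the counts were too few to decide. Among multiciliated cell miRNAs Mir449a, Mir449b and Mir449c were higher, at 0.66, 0.94 and 0.47, and Mir449c did not pass Fisher's exact test. Mir34c stood at -0.0013 and Mir34b at -0.22. These ratios were seen before and are no independent test.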
